A study of Mus musculus with 7 samples.

How the data were processed

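RNA from bronchoalveolar lavage cells was sequenced in 7 libraries, 4 from control mice with Cre in the lysozyme M locus and 3 from mice that also carried floxed Ntn1. Groups were taken from the genotype and titles in the labels. Per the labels' protocols, cells were collected 3 days after intratracheal lipopolysaccharide, neutrophils were depleted with antibodies, RNA was extracted with Trizol and mRNA libraries were made with a KAPA kit. Per the submitters' processing notes, cutadapt 1.15, STAR 2.5.3a, HTSeq and DESeq2 were used with the build GRCm38 (mm10). The versions of HTSeq and DESeq2, the strand setting and the gene annotation are not given in the sources used here.

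The authors deposited 1 table of 16476 genes with a signal column per library, which holds read counts divided by a size factor. Per the file headers, the same table gives the authors' base mean, log2 fold change, its standard error, a test statistic as a score, a p-value and an adjusted p-value. The deposited p-values were missing after adjustment for 650 genes. The authors' log2 fold change divided by its standard error differed from their statistic by over 1% in 1642 of the 16476 genes. Each library's values were whole multiples of 1 step, and 100% of values came out whole within 0.01, so whole reads were recovered by division. The recovered totals were 12332071, 12420215, 13353733 and 9903284 in control replicates 1 to 4 and 12224835, 12255000 and 13182585 in knockout replicates 1 to 3. A count of 0 allows up to 3 reads, which is between 2.66 and 3.76 normalized counts in a library.

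The design fixed before the data were examined named edgeR on raw counts, and limma on log2(value + 1) where a table held normalized values. The table held normalized values, so limma 3.58.1 in R 4.3.3 was used (eBayes with trend) for genes with a mean normalized count of at least 10, which kept 12963 genes. Fold changes are on the log2(normalized count + 1) scale and understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Ntn1, below that minimum, was compared with a 2-sided exact permutation test over the 35 splits of the libraries. All 27 gene lists were fixed before the data were examined. Of these, 25 were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list, which left 0 of the 12 called lists. fry, which asks whether a set's genes move one way on balance, called 3 lists. These were the epithelial (fry adjusted p = 0.00124), natural killer (fry adjusted p = 0.00288) and chemokine (fry adjusted p = 0.0158) lists. The sex-linked list was given as values only, and the eosinophil, basophil and mast cell list had 1 tested member where 3 were required.

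Named genes were chosen by a rule fixed before the data were examined. They are Ntn1, the 12 higher and 12 lower genes with the smallest p among those past the threshold with an absolute log2 fold change of at least 1 and no overlap between groups, leaving out clone names, and up to 2 members per direction of each list; 1 gene named by this rule is not reported here. Members beyond these (Gzma, Ncr1, Apoe, Trem2 and Mki67), Lyz2, Lyz1 and the genes of chromosome segments were chosen after their values were seen. Positions came from GENCODE M21 on GRCm38, which matched 99.81% of the identifiers. For 21 genes the symbol had been turned into a date and was restored from the identifier. Counting without a known strand setting leaves overlapping and antisense genes uncertain.

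Replicates were compared before averaging. The chi-square per gene between libraries of a group lay between 8.63 and 35.5, so none were copies of one another. The pipeline was tested on simulated data with real means, library sizes and dispersions for the comparison of knockouts with controls, over 12971 genes. limma found 48.5% of 66 genes changed 1.5-fold, 68.7% of 67 changed 2-fold and 96.9% of 64 changed 4-fold. Of its calls 4.76% were false, and it made 0 calls where no gene was changed. The simulated genes varied independently and far fewer were changed than the 2813 called in the data, so these shares may not carry over.

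Alternatives were other scalings (TMM, library size, upper quartile), other pseudocounts and filters, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma-voom with and without library weights, the replicate number as a block, a neutrophil score as covariate, and each library left out in turn. edgeR's quasi-likelihood test on the recovered reads called 1385 genes higher and 1535 lower. Chosen after seeing the data were leaving out control replicates 1 and 4, leaving out control replicates 2 and 3, and a correction for transcript length.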

Results

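Cells were washed from the lungs (bronchoalveolar lavage) of C57BL/6 mice 3 days after lipopolysaccharide, a bacterial cell wall component, had been given into the trachea, and neutrophils were removed with antibodies before RNA was taken. The control group comprised 4 libraries from mice carrying the Cre recombinase in the lysozyme M locus, and the knockout group 3 libraries from mice that also carried floxed alleles of Ntn1, the gene for the secreted guidance protein netrin-1. The whole reads behind the deposited normalized counts came to between 9903284 and 13353733 per library. The comparison asks which transcripts differ in airspace cells when myeloid cells lack Ntn1. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries, which may in part be technical.

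Ntn1 (ENSMUSG00000020902, GRCm38 chromosome 11, 68209364 to 68400823) was hardly detected in either group. The control libraries held 1, 4, 9 and 3 reads and the knockout libraries 1, 0 and 1. The normalized count was 4.16 ± 2.86 (SD, n = 4) in controls and 0.639 ± 0.556 (SD, n = 3) in knockouts, a log2 difference of -1.53 (2-sided exact permutation p = 0.0571, the smallest possible with 35 splits being 0.0286). The summed reads, 17 against 2, gave a rate in controls 6.67 times that in knockouts, with a 95% exact interval of 1.58 to 59.5 that covers counting error only. A difference in Ntn1 was therefore not established at this depth. The count covers the whole gene, and the part removed by Cre is not given in the sources used here.

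Lyz2, the lysozyme M gene whose locus carries the Cre, differed between libraries of the control group. Its normalized count was 76927 in control replicate 1 and 118781 in control replicate 4, against 770.1 in replicate 2 and 721.3 in replicate 3. The knockout libraries held 935.9, 1052 and 909.7. The neighbouring paralog Lyz1, with which reads can be shared, stood at 66.5 in control replicate 4 and between 691.3 and 1191 in the other 6 libraries.

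**Figure D1:**
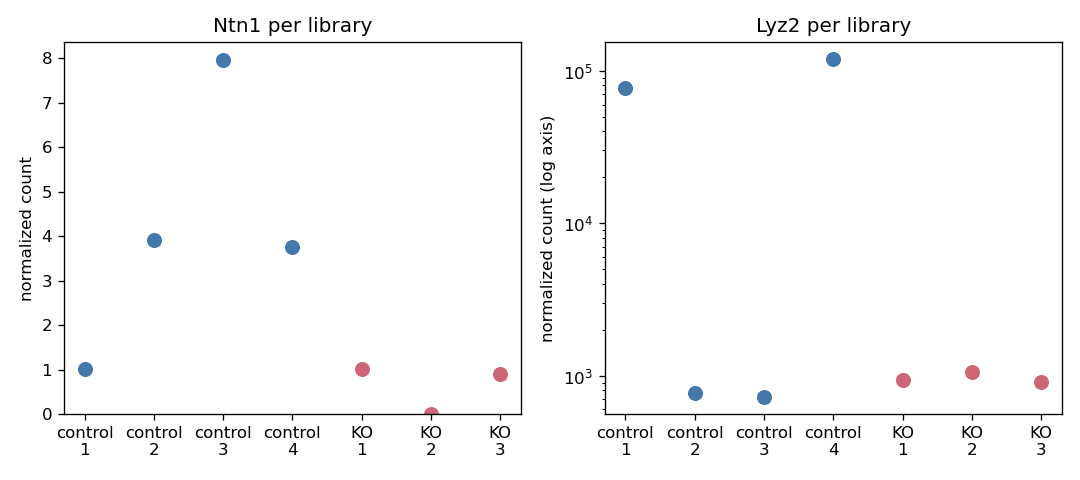
Normalized counts of Ntn1 (left, linear axis) and Lyz2 (right, log axis) in each of the 7 libraries, 1 point per library, controls in blue and knockouts in red. Control replicates 1 and 4 hold 76927 and 118781 for Lyz2, and the other 5 libraries lie between 721.3 and 1052.

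Knockout libraries had more transcript of natural killer cell genes. They had less of 12 of 22 markers of monocytes and recruited macrophages, Apoe and Trem2 among them, and of the RNA sensors Tlr7 and Tlr8. These 2 sensors lie in a segment of distal chromosome X where 8 of the 10 tested genes fell, so the fall is not particular to them. Of 12963 genes tested, 1352 were higher and 1461 lower in knockouts at an adjusted p under 0.05, and 307 and 336 of them differed at least 2-fold. The groups did not overlap for 1324 of the higher and 1408 of the lower genes. Over all genes tested, 4380 had no overlap between groups, where chance gives 5.71%. The first principal component held 51.8% of the variance and separated the groups. These counts rest on few libraries: 694 genes were higher and 810 lower without knockout replicate 2, 893 and 926 without control replicate 2, and 894 and 913 without control replicate 4. With control replicates 1 and 4 left out, a choice made after seeing the data, 622 were higher and 577 lower.

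The natural killer cell markers rose together. All 24 measured members passed the test, over all genes and adjusted over the list alone, with a median log2 fold change of 1.62. Nkg7, a protein of cytotoxic granules, went from 1189 ± 71.7 (SD, n = 4) to 3499.5 ± 171.5 (SD, n = 3) normalized counts (log2 fold change 1.56, SE 0.07, adjusted p = 3.54e-05). Il2rb, a receptor subunit for interleukins 2 and 15, had a log2 fold change of 1.46 (SE 0.11, adjusted p = 0.000316), and Eomes, a transcription factor of natural killer and T cells, one of 1.85 (SE 0.15, adjusted p = 0.000454). Gzma, the granzyme A gene, stood at 3118 ± 994.7 in controls and 16512 ± 1540.5 in knockouts, and Ncr1, an activating receptor of these cells, at 384 ± 126 and 1594 ± 32.7. The set test gave an adjusted p of 1.65e-21 with the preset correlation and an adjusted p of 0.426 with an estimated correlation. Genes within the Klra and Klrc families are near copies, and reads can be split between them.

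T cell markers did not move as a list (median log2 fold change 0.13, adjusted p = 0.118). Over all genes 4 of 20 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell. Trbc1, a T cell receptor constant segment, rose from 481.1 ± 41 to 1067 ± 102.5 normalized counts (adjusted p = 0.000459) and Thy1 by 0.72 on the log2 scale (SE 0.09, adjusted p = 0.00182), while Il7r fell by 0.62 (SE 0.13, adjusted p = 0.0127). Of 9 B and plasma cell markers 1 rose (Ighm) and 1 fell (Blk), the same adjusted over the list alone, and the list was not called (adjusted p = 0.746). With single libraries left out, 0 or 1 rose and 0 to 2 fell. At the preset correlation the T cell list was called higher without control replicate 4 (adjusted p = 0.0438) and without knockout replicate 3 (adjusted p = 0.00806). The estimated correlation of that list was 0.54, and with it the adjusted p was 0.694 over all libraries. Without knockout replicate 2, 3 of its members fell.

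**Figure D2:**
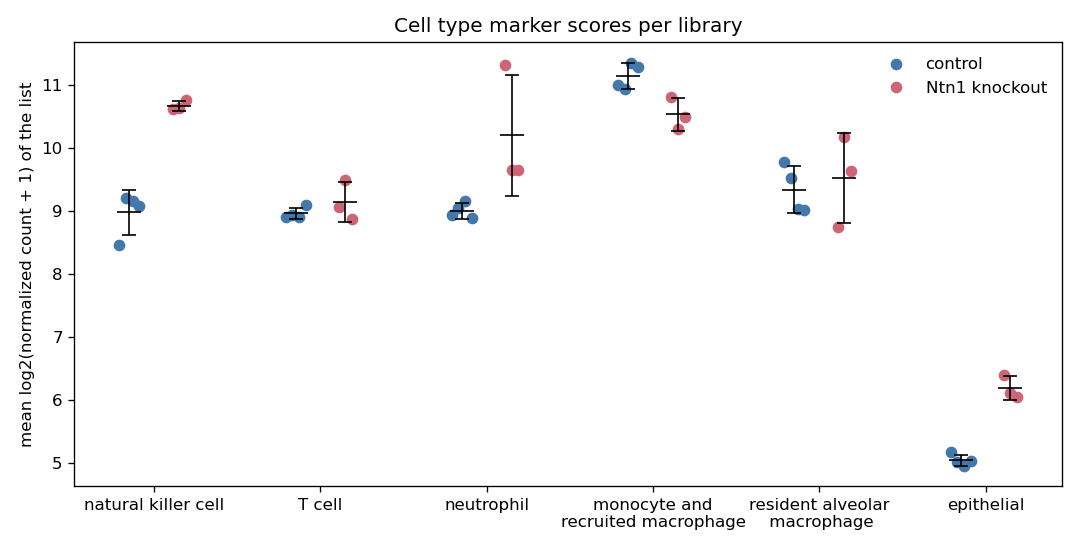
Mean log2(normalized count + 1) over the tested members of 6 marker lists, 1 point per library, with the group mean and SD as black bars, controls in blue and knockouts in red. The natural killer score lies between 8.46 and 9.21 in the 4 controls and between 10.6 and 10.8 in the 3 knockouts, and the neutrophil score of knockout replicate 1 is 11.3.

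More markers of monocytes and recruited macrophages fell than rose. Over all genes 12 of 22 fell and 3 rose, and adjusted over the list alone 14 fell and 4 rose (median log2 fold change -0.68). Apoe, which carries lipids, went from 8248 ± 3015 to 1402 ± 907 normalized counts (log2 fold change -2.65, SE 0.42, adjusted p = 0.00399), and Trem2, a lipid receptor, changed by -1.35 (SE 0.20, adjusted p = 0.00299). Gpnmb and Ms4a7 fell by 1.04 and 1.54 on the log2 scale, while Plac8 rose by 1.00. The set test gave an adjusted p of 0.00149, and an adjusted p of 0.678 with an estimated correlation. The number that fell was 7 without knockout replicate 2. No marker of resident alveolar macrophages passed the test among 22, over all genes or adjusted over the list alone (adjusted p = 0.38 for the list). The lowest p among them was that of Car4, with a log2 fold change of 0.69 (SE 0.29, adjusted p = 0.116). Without knockout replicate 1, 3 members rose and the resident list was called higher (adjusted p = 0.00188 at the preset correlation). The estimated correlation of that list was 0.63, and with it the adjusted p was 0.811 over all libraries. With the neutrophil score as a covariate 5 members rose and the median log2 fold change was 0.99, and without control replicate 4 1 member rose.

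Some neutrophil markers rose in knockouts although neutrophils had been removed. Over all genes 7 of 15 rose and none fell, and 11 rose adjusted over the list alone (median log2 fold change 1.20). Hdc rose by 1.20 on the log2 scale (SE 0.23, adjusted p = 0.00906) and Stfa2l1 by 1.96 (SE 0.42, adjusted p = 0.0127). Knockout replicate 1 stood apart, with a list score of 11.3 against 9.65 in both other knockouts and 8.88 to 9.16 in controls. The set test gave an adjusted p of 0.000158, and an adjusted p of 0.678 with an estimated correlation. Without control replicate 2, and without control replicate 4, 3 members rose; 1 rose without both control replicates 1 and 4, and 0 without both control replicates 2 and 3.

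Most epithelial markers tested rose. Over all genes and adjusted over the list alone, 9 of 14 rose and none fell (median log2 fold change 1.34). Sftpa1, a surfactant protein gene, went from 23 ± 4.35 to 93.2 ± 8.79 normalized counts (log2 fold change 1.99, SE 0.19, adjusted p = 0.000656), and Muc1, a mucin gene, rose by 1.36 (SE 0.19, adjusted p = 0.00264). The set test gave an adjusted p of 0.00012, and an adjusted p of 0.144 with an estimated correlation. Of 14 dendritic cell markers 4 rose, Ccl17 and Ccl22 among them, and 1 fell (Wdfy4), with 5 and 1 adjusted over the list alone (adjusted p = 0.135 for the list). Of 7 endothelial and stromal markers 1 rose (Pecam1) and 1 fell (Kdr), with 2 and 1 adjusted over the list alone (adjusted p = 0.572). The median log2 fold change of that list was -0.03, its mean 0.31 and its test pointed up. Of the eosinophil, basophil and mast cell markers only Kit was abundant enough to test, and it rose by 1.14 on the log2 scale (SE 0.13, adjusted p = 0.00115). No erythroid gene passed the test among 7, over all genes or adjusted over the list alone (median log2 fold change 2.04, adjusted p = 0.0794), and the score of knockout replicate 1 was 11.9 against 4.85 to 9.08 in the other libraries. Slc4a1 had the lowest p of that list (adjusted p = 0.139). The erythroid list was called higher without control replicate 3 (adjusted p = 0.0217), knockout replicate 2 (adjusted p = 0.0328) or knockout replicate 3 (adjusted p = 0.02), at the preset correlation; the estimated correlation of that list was 0.99, and with it the adjusted p was 0.678 over all libraries. With single libraries left out, 2 to 5 dendritic cell markers rose and 0 or 1 fell, and 1 or 2 endothelial and stromal markers rose and 0 or 1 fell. No dendritic cell marker passed with the title number as a block or with the neutrophil score as a covariate.

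Genes of lipid handling and of the uptake of dying cells went both ways. Of 22 lipid handling genes 5 rose and 7 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.78, median log2 fold change 0.06, mean -0.003); 4 fell without control replicate 4 or knockout replicate 2. Abca1, which exports cholesterol, fell by 1.46 on the log2 scale (SE 0.20, adjusted p = 0.00204) and Npc1 by 0.53 (SE 0.08, adjusted p = 0.00339), while Scd1, a desaturase, rose by 1.62 (SE 0.22, adjusted p = 0.00202) and Dgat1 by 1.04 (SE 0.13, adjusted p = 0.00165). Of 16 efferocytosis genes 3 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.555, median log2 fold change -0.13, mean 0.01). Timd4, a phosphatidylserine receptor, rose from 16.9 ± 9.44 to 155.7 ± 55.9 normalized counts (log2 fold change 3.20, SE 0.37, adjusted p = 0.00115), and Itgb3 rose by 0.99. Stab1, a scavenger receptor, fell by 1.59 (SE 0.20, adjusted p = 0.00174) and Lrp1 by 1.38 (SE 0.15, adjusted p = 0.000963). Of 20 sterol biosynthesis genes 7 rose, Sc5d and Lss among them, and 1 fell (Mvd), the same adjusted over the list alone (median log2 fold change 0.35, adjusted p = 0.000699, and adjusted p = 0.678 with an estimated correlation). The number that rose was 3 without any one of control replicates 1, 2 and 4 or knockout replicate 1, 2 without knockout replicate 2, 1 without both control replicates 1 and 4, and 3 without both control replicates 2 and 3.

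Among chemokines 7 of 23 rose and 1 fell, the same adjusted over the list alone (median log2 fold change 0.62, adjusted p = 0.00155, and adjusted p = 0.426 with an estimated correlation). Cxcl10, which attracts T and natural killer cells, rose by 0.88 on the log2 scale (SE 0.11, adjusted p = 0.00152) and Cxcl16 fell by 0.91 (SE 0.14, adjusted p = 0.00324). Xcl1, also on the natural killer list, rose by 1.13. Of 24 type I interferon response genes 3 rose, Isg20 and Isg15 among them, the same adjusted over the list alone (median log2 fold change 0.28, adjusted p = 0.00757, and adjusted p = 0.678 with an estimated correlation). Of 22 interferon gamma response genes 3 rose and 1 fell, 4 and 1 adjusted over the list alone (median 0.20, adjusted p = 0.0379, and adjusted p = 0.678 with an estimated correlation); Irf8 and Socs1 rose and Ciita, the activator of MHC class II genes, fell. Of 21 genes of NF-kB and Toll-like receptor signalling 3 rose, Myd88 and Nfkb1 among them, and 2 adjusted over the list alone (median 0.29, adjusted p = 0.0178, and adjusted p = 0.678 with an estimated correlation). Of 20 proinflammatory cytokines and enzymes 2 rose (Hmgb1 and Csf3), the same adjusted over the list alone, and the list was not called (adjusted p = 0.291). Of 15 alternative activation genes 5 rose, Tgfb1 and Ccl17 among them, and 1 fell (Tgm2), with 5 and 2 adjusted over the list alone (adjusted p = 0.204). Of 14 MHC class II and costimulation genes 1 rose (Cd80) and 3 fell, Ctss and Ciita among them, with 1 and 6 adjusted over the list alone (adjusted p = 0.0863).

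Several of these calls depended on 1 library. Without control replicate 3 the type I interferon (adjusted p = 0.0554), interferon gamma (adjusted p = 0.167) and NF-kB (adjusted p = 0.0867) lists were not called. Without knockout replicate 1 the type I interferon (adjusted p = 0.0704) and interferon gamma (adjusted p = 0.0606) lists were not called, and without knockout replicate 2 the interferon gamma list was not (adjusted p = 0.0508). With single libraries left out, 1 to 8 type I interferon genes rose and 0 or 1 fell, 2 to 4 interferon gamma genes rose and 0 to 2 fell, and 1 to 3 NF-kB genes rose. At the preset correlation the MHC class II list was called lower without control replicate 2 (adjusted p = 0.0114) or control replicate 3 (adjusted p = 0.041), and 1 to 6 of its members fell. The estimated correlation of that list was 0.42, and with it the adjusted p was 0.678 over all libraries. Of the proinflammatory genes 1 or 2 rose and 0 to 2 fell, and of the alternative activation genes 3 to 5 rose and 0 or 1 fell. With the neutrophil score as a covariate 0 type I interferon genes (median 0.05) and 0 NF-kB genes (median 0.13) rose, as did 0 NF-kB genes with the title number as a block. The type I interferon score was 10.9 in knockout replicate 1, where neutrophil markers were highest, 10.6 and 10.3 in the other knockouts and 10.1 to 10.4 in controls. Of the alternative activation genes 1 rose with the title block and 1 with the covariate.

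Of 25 cell cycle genes 11 rose and none fell over all genes, and 15 rose adjusted over the list alone (median log2 fold change 0.55, adjusted p = 1.1e-05, and adjusted p = 0.678 with an estimated correlation). Mcm6, part of the replicative helicase, rose by 0.63 on the log2 scale (SE 0.09, adjusted p = 0.00278) and Cdc20, an activator of mitotic exit, by 0.97 (SE 0.16, adjusted p = 0.00515), whereas Mki67 had a log2 fold change of -0.13 (SE 0.17, adjusted p = 0.629). The list score of knockout replicate 1 (8.45) lay below that of control replicate 1 (8.60), and the scores gave an exact permutation p of 0.0857. The number that rose was 20 without knockout replicate 1, 4 without knockout replicate 2 or 3 or control replicate 2, 5 without control replicate 3 or 4, 3 without both control replicates 1 and 4, and 2 without both control replicates 2 and 3. It was 1 with the title number as a block and 19 with the neutrophil score as a covariate. Of 23 hypoxia and glycolysis genes 1 rose (Ndrg1) and 2 fell (Hk2 and Egln3), with 1 and 1 adjusted over the list alone (median log2 fold change -0.20, adjusted p = 0.0202, and adjusted p = 0.678 with an estimated correlation). Of 10 mitochondrially encoded genes 1 rose (mt-Nd6), the same adjusted over the list alone (median 0.26, adjusted p = 0.0256, and adjusted p = 0.678 with an estimated correlation). The hypoxia list was not called without control replicate 4 (adjusted p = 0.0931), knockout replicate 1 (adjusted p = 0.101) or knockout replicate 2 (adjusted p = 0.0642), and 0 to 3 of its members fell with single libraries left out. The mitochondrial list was not called without control replicate 3 (adjusted p = 0.0554), knockout replicate 1 (adjusted p = 0.0606) or knockout replicate 2 (adjusted p = 0.0642). Of 22 immediate early and handling stress genes 5 rose, Jund and Nr4a1 among them, the same adjusted over the list alone (adjusted p = 0.204), and 0 to 3 fell with single libraries left out. Among 6 netrin receptor genes abundant enough to test, Dscam rose by 1.17 on the log2 scale (SE 0.32, adjusted p = 0.0326) and Adora2b by 0.52 (SE 0.15, adjusted p = 0.0355), the same adjusted over the list alone, and the list was not called (adjusted p = 0.21). Neither of these 2 passed without control replicate 4, knockout replicate 2 or knockout replicate 3, and 1 passed without control replicate 1, control replicate 2 or knockout replicate 1. Of the sex-linked genes, not tested as a list, Ddx3y, Eif2s3y and Kdm5d had log2 fold changes of -0.06, 0.15 and 0.00, and Uty fell by 0.45 (SE 0.11, adjusted p = 0.0234).

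Among the higher genes with the smallest p, Nkg7, Il2rb, Klrc1, Eomes and Xcl1 belong to the natural killer list. The others were Tspan13, Ptprcap, Trbc1, Serpinb9, Dusp5, Sh2d1a and Gimap6, with log2 fold changes from 1.00 to 1.73. Serpinb9, an inhibitor of granzyme B, went from 2756 ± 424 to 7587 ± 315 normalized counts. The lower genes with the smallest p included Tlr7 and Tlr8, sensors of single-stranded RNA in endosomes. Tlr7 went from 6297 ± 673 to 2071 ± 263 normalized counts (log2 fold change -1.61, SE 0.11, adjusted p = 0.000232) and Tlr8 from 2383 ± 379 to 878.5 ± 40.2 (log2 fold change -1.43, SE 0.12, adjusted p = 0.000459). Hccs, which attaches heme to cytochrome c, fell by 1.04 (SE 0.06, adjusted p = 0.00013). These 3 genes lie close together at the distal end of chromosome X, where 8 of the 10 tested genes from Gm8817 (start 167063194) to BC022960 (end 169370003) fell. Olfr56 on chromosome 11 (48978889 to 49135387) went from 385.8 ± 56.9 to 11.7 ± 6.67 normalized counts (log2 fold change -5.04, SE 0.30, adjusted p = 0.000133); it overlaps other genes, so its reads may not all be its own. The remaining 8 lower genes were Stard9, Plekhn1, Slc6a8, Fnip2, Myo5a, Pgap1, Cd163l1 and Cd93, with log2 fold changes from -1.03 to -1.56.

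**Figure D3:**
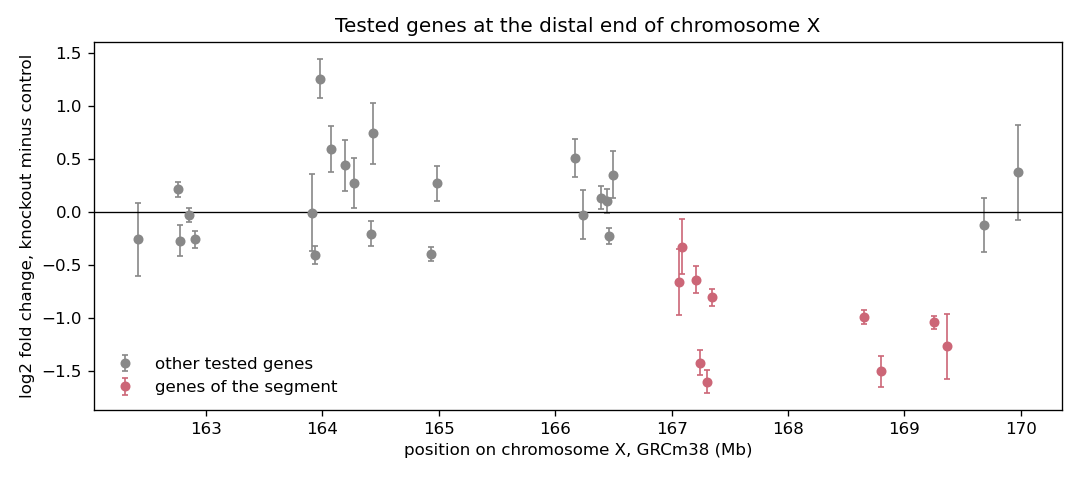
Log2 fold change (knockout minus control, with SE) of tested genes against position on chromosome X in GRCm38, in Mb. The 10 genes from Gm8817 to BC022960, in red, lie between -0.33 and -1.61.

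Called genes differed in transcript length. Among 11631 protein-coding genes, ordered by length in 5 equal groups, 390 of the shortest group were higher and 85 lower in knockouts, and 147 of the longest group were higher and 522 lower. The rank correlation of length with each library's deviation was 0.197 ± 0.101 (SD, n = 4) in controls and -0.206 ± 0.128 (SD, n = 3) in knockouts (2-sided exact permutation p = 0.0286, the smallest possible). Transcripts annotated as sense intronic fell in 10 of 26 cases and rose in 0, with a median log2 fold change of -0.91. Larger noncoding or unverified classes also fell more often than they rose. Of 212 transcripts of unverified status (TEC) 76 fell and 6 rose (median -0.90). Of 202 antisense transcripts 44 fell and 10 rose, and of 278 annotated as lincRNA 49 fell and 13 rose. These trends ran with the groups, so a source in the cells cannot be told apart from one in the libraries. Of the calls, 2287 kept their direction and passed again after a length correction chosen after seeing the data, and 526 did not pass.

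**Figure D4:**
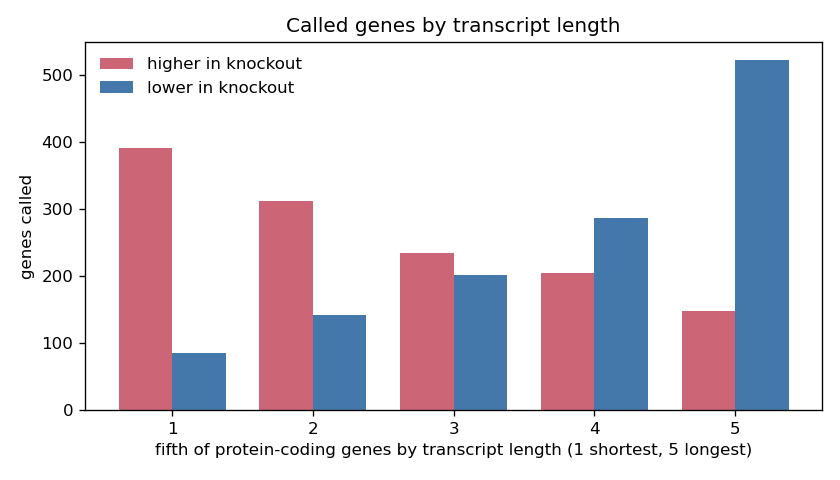
Number of protein-coding genes called higher (red) or lower (blue) in knockouts in each of 5 equal groups by transcript length, from the shortest (1) to the longest (5). The shortest group holds 390 higher and 85 lower genes and the longest 147 and 522.

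The authors' deposited table gave 1412 genes higher and 1570 lower at an adjusted p under 0.05. Of the 2852 of these that were tested here, 2613 were also called here and all 2613 had the same direction. Another 200 genes were called here only and 239 by the authors' deposited table only. The authors' deposited table lists Tlr7 at a log2 fold change of -1.49. For Ntn1 it gives a log2 fold change of -0.31 (SE 0.16), with an unadjusted p of 0.0478 and no adjusted p. DESeq2 on the recovered reads gave -2.72 for Ntn1 with the same unadjusted p. The deposited log2 fold change of Ntn1 therefore differs from the DESeq2 estimate that goes with the same p. How it was computed is not given in the sources used here, so it cannot be set against the -1.53 found here.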

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

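Chosen after the results were seen were the tests of the copy number and of sex for the X segment, of a swap for Lyz2, and the 3 tests for the natural killer markers; the other tests of this part were set before their values were computed, with the patterns themselves already seen.

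Of 118 sets of 4 control values examined, 10 had 1 library far from the other 3, where chance alone gives about 1 in 20. Control replicate 2 held 65.6 normalized counts of Itga3. Control replicate 3 held 629 of Itga6, 652 of Hdc and 3490 of Nfkb1, control replicate 1 held 18100 of Lrp1 and control replicate 4 held 1380 of Ddx3y. Control replicate 1 had a natural killer score of 8.46. Control replicate 3 had scores of 8.24 for proinflammatory cytokines and enzymes, 10.1 for the type I interferon response and 10.9 for NF-kB and Toll-like receptor signalling.

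Chance as the source of the gene counts was tested by regrouping the libraries. Only 1 of the 35 splits, the real one, gave as many higher genes (1352, highest other 0). The same held for lower genes (1461, highest other 0). A share of 1 in 35 is the smallest possible here, so chance is argued against for these counts but not excluded. The other splits mix the groups, so a difference between the groups widens their spread and lowers their counts. The number of gene lists gives no argument against chance. Of the 35 splits, 11, the real one included, called at least 12, the real value, and the highest other called 16. The number of lists called is therefore no evidence of a difference between the groups.

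All 24 natural killer markers were higher in knockouts. A lower share of the main cell type would raise other types alike. The natural killer score rose by 1.51 more than the T cell score (exact permutation p = 0.0286). List medians were also low for B cell (-0.16), endothelial and stromal (-0.03) and dendritic cell markers (0.42). Epithelial (1.34), neutrophil (1.20) and erythroid (2.04) medians came nearer to, or above, that of the natural killer list. The types did not all move alike, but a lower share of the main type is not excluded as part of the cause. The length trend is argued against as the whole cause, since the list's median of 1.62 was 1.57 after the length correction. With the neutrophil score as a covariate the median was 1.66. That score did not overlap between groups (8.88 to 9.16 in controls, 9.65 to 11.3 in knockouts). This adjustment thus rests on differences within groups and decides little about leftover neutrophils. A larger share of natural killer cells in the lavage of knockouts is a candidate explanation, as is more transcript per cell, and no value here separates them. The antibody depletion step, if it varied between groups, also stays open as untested.

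Lyz2 was 165 times higher in the highest than in the lowest control library. A different share of macrophages is argued against, since the largest such ratio among 23 abundant macrophage and monocyte markers was 2.67. A high control library swapped into the knockout group was not seen, as the highest knockout library held 1052 normalized counts. This was known before the test was set, and a swap among libraries with low Lyz2 would leave it unchanged. The test therefore does not decide about other swaps. A difference at the locus may be the cause: only 1 other gene with a mean of at least 50 (Slc15a2, ratio 73.5) reached a ratio of 50. That limit cannot see moderate differences, so differences elsewhere between these controls are not excluded. The MHC class II score, for example, was 10.5 in control replicates 1 and 4, 9.93 in replicate 2 and 10.1 in replicate 3. One hypothesis is that the number of Cre-carrying Lyz2 alleles differed between control mice, which the labels do not give.

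In the 10 tested genes of the distal X segment the median log2 fold change was -1.02, against 0.10 in the 21 genes of the 5 Mb before it. With the monocyte score as a covariate the median stayed at -1.06. That score did not overlap between groups (10.9 to 11.4 in controls, 10.3 to 10.8 in knockouts). The adjustment thus rests on differences within groups and decides little about a lower share of monocytes. A difference in sex is argued against, since the lowest control library had 0.95 times the knockout mean of Y-linked reads. An extra copy of the segment in control mice may explain it, but this cannot be told apart from regulation. The mean over the 10 genes was -1.03, with a 95% t interval across genes of -1.33 to -0.73, which includes a doubling. That interval takes the genes as independent and does not measure the spread between libraries. For 6 of the 10 genes the gene's own interval left out a doubling. The copy number test replaced an earlier one whose bounds had been set around the median already seen. The segment's limits were chosen from these data, and an effect of the Ntn1 genotype on these genes stays open as untested.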

How the results depend on the processing

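Leaving out control replicates, and the length correction, were chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times of 1352 and 1461 under the other scalings, pseudocounts, filters and tools. They were 425 and 372 with the title number as a replicate block and 607 and 606 with the description number, each on 6 libraries, and 604 and 554 with the neutrophil score as covariate. They were 622 and 577 without control replicates 1 and 4, 614 and 619 without control replicates 2 and 3, and 307 and 336 at 2-fold or more. Each library left out in turn gave 694 to 1173 higher and 810 to 1293 lower genes. Calls shared with the authors' deposited table (2613) were 792 and 1192 under the 2 blocks, 903 with the covariate, 1146 and 1153 without the 2 pairs of controls, and 1472 to 2199 with single libraries left out. Fewer libraries or residual degrees of freedom enter these fits. The neutrophil score also did not overlap between groups, so the fit with it separates score and genotype poorly. Beyond that the cause was not tested. No pairing of the samples by number was seen: the correlations of same-numbered libraries were -0.23, -0.025 and -0.19 by title and -0.077, -0.29 and 0.076 by description. These few correlations, of deviations from small group means, cannot exclude pairing. Of 12 lists called, 0 were called with estimated correlations and 3 by fry, and 9 to 14 with single libraries left out. The other list calls of this part use the preset correlation. Natural killer markers rose in 21 to 24 cases in each setting. Neutrophil markers (7) rose in 4 cases with robust edgeR or limma-voom, 3 and 4 with the title and description blocks and 0 with their own score as covariate. Of the monocyte markers (12) 7 fell with the title block. Epithelial markers (9 of 14) rose in 4 of the 6 cases left at a mean of at least 50, 4 with the covariate and 5 without control replicates 2 and 3. Chemokines (7) rose in 4 cases with the title block, sterol genes (7) in 1 with that block and 1 with the covariate, and cell cycle genes (11) in 20 with library weights and 5 with the description block. Without control replicates 2 and 3 the type I interferon (adjusted p = 0.0771), interferon gamma (adjusted p = 0.259), NF-kB (adjusted p = 0.181) and mitochondrial (adjusted p = 0.204) lists were not called, and the MHC class II (adjusted p = 3.78e-05) and erythroid (adjusted p = 0.00393) lists were. Without control replicates 1 and 4 the hypoxia list was not called (adjusted p = 0.305), and the T cell (adjusted p = 0.0451) and proinflammatory (adjusted p = 0.045) lists were. The title block ended the hypoxia call (adjusted p = 0.0984) and called the T cell list (adjusted p = 0.0408); a mean of at least 50 ended the interferon gamma (adjusted p = 0.0846) and mitochondrial (adjusted p = 0.0853) calls. Without the filter the erythroid list was called (adjusted p = 0.0382). So was the eosinophil, basophil and mast cell list, then with 4 tested members (adjusted p = 0.0256). The length correction called MHC class II (adjusted p = 0.0334) and ended the mitochondrial call (adjusted p = 0.156). With the covariate and the title block, 3 lipid handling genes rose and 2 fell in each, 0 mitochondrial genes rose, and 1 and 3 immediate early genes rose. With the title block 0 proinflammatory and 0 netrin receptor genes rose. Ntn1 kept its direction, but its size depended on the pseudocount (-2.83 at 0.1 and -0.65 at 5, -2.72 in DESeq2, and -1.21 to -1.92 with single libraries left out); its adjusted p was 0.104 in limma without the filter, and DESeq2 gave an unadjusted p of 0.0478 and no adjusted one. It fell below the filters of edgeR and limma-voom, and was not run with a block or covariate. None of the 79 named genes called here reversed its direction in the settings run; the sign of genes not called, such as Kdm5d, did change. Of these 79, 26 lost the call with the title block, 26 with the neutrophil covariate and 23 without control replicates 1 and 4. At 2 to 17 reads per group, depth limits what can be said of Ntn1.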

Other observations

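The tests in this part were chosen after the results were seen.

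Gene families sharing the letters of their symbol were compared with all other genes, and 8 of 209 families with at least 8 tested members were called with the preset correlation and 0 with an estimated one (adjusted p = 0.865 for each of the 8). All 9 tested Gimap genes, GTPases of lymphocytes, rose, with a median log2 fold change of 0.98. Of 66 genes with symbols in Rpl, the letters used for proteins of the large ribosomal subunit, 42 rose and 0 fell (median 0.36). Of 60 with symbols in Rps, used for the small subunit, 31 rose and 1 fell (median 0.33). Letters alone set these families, so genes that share them without encoding a ribosomal protein are counted too. Of 8 Setd genes 4 fell and 0 rose (median -0.31, adjusted p = 0.0168 with the preset correlation), and of 8 Kmt genes 3 fell and 0 rose (median -0.35, adjusted p = 0.0178). The other called families were Klra (9 of 13 rose), Mcm (3 of 10 rose) and Cdkn (3 of 8 rose), with 0 genes that fell. After the length correction the medians of Setd and Kmt were -0.24 and -0.22, with 3 genes of each that fell. Ribosomal protein transcripts are short, and after the length correction 31 Rpl and 22 Rps genes rose, with medians of 0.27 and 0.21.

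Slc15a2, a peptide transporter, stood at 6.20 normalized counts in control replicate 3 and 8.65 in knockout replicate 2, against 193.7 to 455.2 in the other 5 libraries.

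Several of the largest changes lay on chromosome 11, as Ntn1 does. The transcript 9930111J21Rik2 (49015874 to 49051242) had a log2 fold change of -6.08, the overlapping Olfr56 one of -5.04 and Timd4 one of 3.20. A chromosome segment of another strain carried along with the floxed allele was tested as a hypothesis. Within 25 Mb of Ntn1, 5 of 519 tested genes were called with an absolute log2 fold change of at least 2, against 81 of 12444 elsewhere (odds ratio 1.48, 95% interval 0.467 to 3.63, Fisher's exact p = 0.4). The excess was not established, and these few genes cannot decide the hypothesis.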
